A study of Mus musculus with 4 samples.

How the data were processed

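RNA was sequenced from haploid cells that had been stained with Hoechst dye and sorted by fluorescence from testes of mice aged 23 days, per the labels' protocols. The libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols, and whether reads were counted by strand is not given in the sources used here, so a gene and an overlapping antisense gene cannot be told apart. The deposited values are FPKM, computed by the authors. The submitters' processing notes name TopHat2 2.0.6, Cufflinks 2.0.2, Cuffdiff and the mouse genome build mm9. The role and settings of each tool are not given in the sources used here. The strain label reads DBA/C57/ICR, DBA/C58/ICR, DBA/C59/ICR and DBA/C60/ICR for wild-type library 1, knockout library 1, wild-type library 2 and knockout library 2, and no use was made of it. The labels do not say whether libraries of a genotype came from separate animals.

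Each library had a table of 23021 entries covering 22552 symbols, 259 of which stood on more than 1 entry and were summed. Zeros were listed as such. Groups and library numbers were taken from the sample titles. Genes with a mean FPKM of at least 1 over the 4 libraries were tested, 9124 in all. Values were transformed as log2(FPKM + 1), so each fold change is on that scale and understates the change of low genes. The FPKM were not rescaled between libraries. Genotype was the only term in a limma 3.58.1 fit in R 4.3.3 with empirical Bayes moderation and a mean-variance trend (residual degrees of freedom 2, prior degrees of freedom 3.84). Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Errors of log2 changes are standard errors from the same fit.

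Gene lists, 15 in number, were fixed before the data were examined, as were the named-gene rule and the other settings to be tried. The lists were tested with camera in limma at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 15 lists. With an estimated correlation camera judges its statistic on the 2 residual degrees of freedom. On so few a list can hardly pass, so a value above the threshold there does not show that a list stayed unchanged. Older symbols were matched where a list gave them, and members absent from the tables were left out. The named genes were Sox30, the 12 genes per direction with the largest log2 change among those past the threshold whose knockout values both lay outside the wild-type range, and up to 4 members of each list past the threshold, topped up to 2 with the members of highest mean FPKM. Predicted genes with clone-like symbols were passed over among the 12, 3 among the falls and 5 among the rises. Other genes are marked in the text as picked after their values were seen.

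The settings chosen beforehand were pseudocounts of 0.1 and 5, no filter on low values, a mean FPKM of at least 5, median-ratio scaling, quantile normalization, robust empirical Bayes, no mean-variance trend, leaving out each library in turn, the library number as a replicate block, only symbols listed once, an adjusted p under 0.1 and a rule of 2-fold in each pair of libraries. A lowess correction of each library on transcript GC content (span 0.3) and a crossed pairing of library numbers were added after seeing the data. With 1 library left in a genotype, its spread was taken to be that of the other genotype.

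Chromosome, transcript length and GC content were taken by symbol from GENCODE M21, whose genome build differs from that of the authors, so no coordinates are given. They were found for 22130 of 22552 symbols and GC content for 98.6% of the genes tested. Chromosomes were compared with Fisher's exact test, two-sided and adjusted over 42 tests.

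Read counts were not used here, and no counting intervals are given. Where FPKM below 1 are worth few fragments, the ratio of a gene's values in 2 libraries falls on steps that give the relative depth. With a tolerance of 0.01 on the log2 scale, 21.6%, 13.7% and 13.0% of low genes in wild-type library 2, knockout library 1 and knockout library 2 fell on the steps against wild-type library 1, where about 2.12%, 1.96% and 1.95% do so at other shifts. In simulated reads the method was off by at most 0.666%.

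The fit was tested on simulated data with the measured levels and spreads of the 9124 genes, in 20 simulated sets for each design. With 200 genes changed by 1 or 2 on the log2 scale, 0% were recovered and 0 false calls were made. The sizes were then raised: with 200 genes changed by 2, 4 or 6 on the log2 scale, 32.0%, 76.5% and 88.0% were recovered, with 4 false calls on average. With 1000 genes changed by 1, 2, 4 or 6, recovery was 16.6%, 64.6%, 90.6% and 97.2%, and 4.18% of calls were false. Changes of 2-fold were thus mostly missed in the simulated sets. Changed genes were drawn only from those above a set wild-type level, and simulated values could go below 0, which measured values cannot. All changes in the sets of 1000 were falls. The recovery rates therefore do not cover low genes or falls that end at 0, and those of the sets of 1000 do not cover rises. In 100 simulated sets camera called 0 unchanged lists and 100 lists shifted by -1. These sets carried over the levels and spreads of single genes, not the correlation between members of a list. In the measured data the estimated correlation ranged from -0.043 for the spermatogonia markers to 0.618 for ribosomal proteins. The simulation therefore cannot show how often camera at the preset correlation would call unchanged lists of correlated genes. Python 3.11.15, pandas 2.3.3 and scipy 1.17.1 were used for the remaining steps.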

Results

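Transcript levels were measured by RNA sequencing in haploid cells sorted from the testes of mice at 23 days after birth, an age at which the design text places the most advanced haploid cells at step 3 of spermatid development. There were 4 libraries, 2 from wild-type mice and 2 from mice lacking Sox30, a gene for a transcription factor of the SOX family. Levels were given as FPKM, a measure of fragments scaled by transcript length and by the mapped fragments of the library, for 22552 gene symbols in each library. Read counts were not part of the tables used here, so the absolute depth of the libraries is unknown. Relative depth could be read from the steps between the lowest values: taking wild-type library 1 as 1, it was 1.39 for wild-type library 2, 1.24 for knockout library 1 and 1.16 for knockout library 2.

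The libraries separated by genotype. Across the 9124 genes tested, the Pearson correlation of log2(FPKM + 1) was 0.976 between the wild-type libraries and 0.940 between the knockout libraries, and lay between 0.787 and 0.818 for pairs of different genotype (correlations across genes, which are not independent replicates). The first principal component held 81.3% of the variance and placed the wild-type libraries at -71.2 and -70.5 and the knockout libraries at 59.1 and 82.6. The knockout libraries held fewer detected transcripts. Symbols listed at 0 numbered 6414 and 5915 in wild-type libraries 1 and 2, against 9329 and 11112 in knockout libraries 1 and 2. The 100 most abundant genes took 33.4% and 29.5% of all FPKM in the wild-type libraries and 37.9% and 46.7% in the knockout libraries.

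The targeted gene came first, as a check of the labels. Sox30, on chromosome 11, stood at 11.4 and 16.2 FPKM in the wild-type libraries and at 1.46 and 3.16 FPKM in the knockout libraries. It fell by 2.19 on the log2 scale (SE 0.43, limma adjusted p = 0.0219), and transcript remained detectable in both knockout libraries. The change was -1.36 with a pseudocount of 5 and -1.67 with quantile normalization (limma adjusted p = 0.0489). The labels do not say which part of the gene was removed. Without wild-type library 1 the change was -2.43 (limma adjusted p = 0.295) and without wild-type library 2 it was -1.95 (limma adjusted p = 0.357), neither past the threshold. Testing all genes with no filter on low values gave limma adjusted p = 0.0660.

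The comparison asks which genes differ in level between haploid cells sorted from knockout and from wild-type mice. It cannot tell a direct dependence on Sox30 from a halt in development or from a different mix of sorted cells. Far more genes were lower than higher in the knockout: of 9124 genes tested, 1221 fell and 178 rose at a limma adjusted p under 0.05. The fallen genes had a median log2 change of -2.61 and the risen genes of 1.69. All 1399 changed by at least 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes. Of the fallen genes, 779 had a knockout mean under 1 FPKM and 274 were listed at 0 in both knockout libraries, whereas 4 of the risen genes were listed at 0 in both wild-type libraries. Genes strongly transcribed in the wild type were included: among 1021 genes with a wild-type mean of 100 FPKM or more, 172 fell and 18 rose. For 5550 genes, 60.8% of those tested, both knockout values lay on the same side of both wild-type values, where chance gives 33.3% for a single gene. All genes share the same libraries, and a shift common to the libraries of a genotype separates many genes at once. The excess is therefore no count of changed genes.

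**Figure D1:**
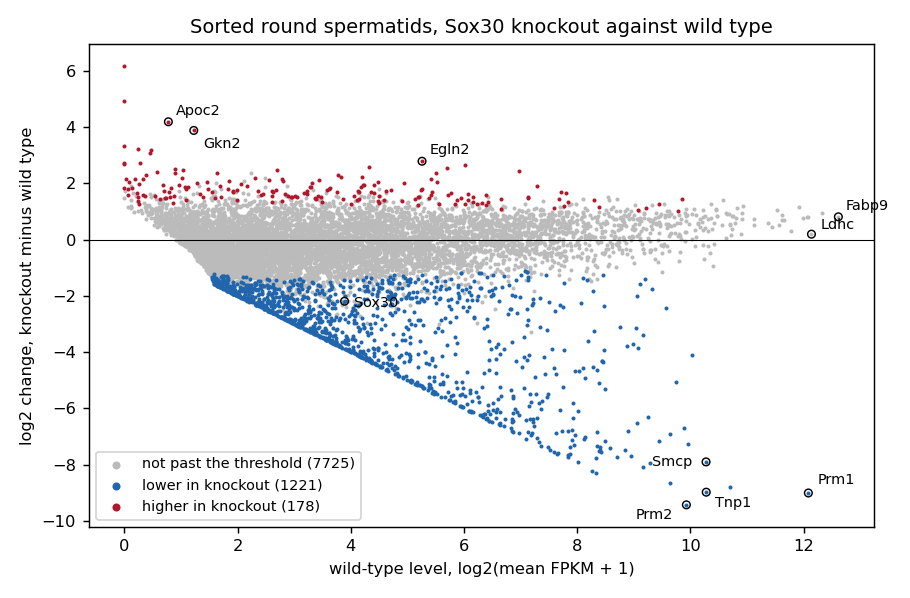
Log2 change of FPKM + 1 in the knockout against wild type (vertical axis) for each of the 9124 genes tested, by wild-type level as log2 of mean FPKM + 1 (horizontal axis). Blue points are the 1221 genes that fell, red points the 178 that rose and grey points the others; circled genes are named, and the lower edge of the cloud is formed by genes at or next to 0 in the knockout.

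These counts rest on 2 libraries per genotype, and leaving out 1 library moved them far. Without wild-type library 1, 386 genes fell and 0 rose in the limma fit, with 1517 genes at an unadjusted p under 0.05. Without wild-type library 2, 0 genes passed in either direction, in any list described here, with 1412 genes at an unadjusted p under 0.05. Without knockout library 1, 3071 fell and 984 rose, and without knockout library 2, 1846 fell and 898 rose. In these last fits the spread came from the wild-type pair alone, whose log2 values differed with an SD of 0.491 against 0.852 for the knockout pair. Quantile normalization changed the balance of the calls to 1012 lower and 608 higher, 62.5% lower against 87.3%. It also moved the median change of all genes from -0.23 to 0.17. Changes followed the GC content of transcripts, with a median of -0.70 in the lowest of 5 equal GC classes and 0.36 in the highest, and after a GC correction chosen after seeing the data 1161 genes fell and 319 rose. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical.

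On the log2(FPKM + 1) scale the deepest falls among named genes were in genes that package the sperm nucleus. The wild-type level caps a fall on that scale, so this does not rank how completely transcripts were lost. Prm2 and Prm1, the protamines, and Tnp1 and Tnp2, the transition proteins that precede them on sperm DNA, had the largest decreases among named genes by that measure. Prm2 fell from 1228 and 719 FPKM in the wild type to 0.288 and 0.460 FPKM in the knockout, a log2 change of -9.42 (SE 0.37, limma adjusted p = 4.8e-04). Prm1 fell from 5537 and 3145 FPKM to 25.2 and 1.54 FPKM (limma adjusted p = 0.00320). Tnp1 went from 1516 and 968 FPKM to 4.82 FPKM in knockout library 1 and was listed at 0 in knockout library 2. Hils1, a linker histone of spermatids, fell from 752 and 496 FPKM to 3.40 and 0.402 FPKM, and Hmgb4 fell from 308 and 208 FPKM to 0.119 FPKM and a value of 0. In the whole chromatin condensation list, 15 of 32 tested members fell, 1 rose and 16 did not pass; adjusted over the list alone the counts were 19 and 2. The member that rose was Hist1h1t, the testis linker histone H1t, at 1.06 and 1.31 FPKM in the wild type and 4.81 and 10.1 FPKM in the knockout. The list lay below the other genes, with a median log2 change of -1.45 (camera adjusted p = 6.5e-06; adjusted p = 0.555 with an estimated correlation). The size of that median depended on the settings: it was -4.04 with a mean FPKM of at least 5, -2.45 with a pseudocount of 0.1 and -0.73 with a pseudocount of 5.

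Acrosome genes fell as a group. Of 55 tested members 30 fell, 0 rose and 25 did not pass; adjusted over the list alone, 33 fell. The median log2 change was -2.34 (camera adjusted p = 2.3e-10; adjusted p = 0.555 with an estimated correlation). Iqcf1, at 222 and 142 FPKM in the wild type, and Izumo2, at 150 and 122 FPKM, were listed at 0 in both knockout libraries. Lyzl6, of the lysozyme-like family, fell from 422 and 341 FPKM to 2.93 and 0.260 FPKM, and Tmco2 from 297 and 257 FPKM to 2.76 and 0.117 FPKM. Other acrosome genes, named after their values were seen, moved less: Acr, the gene for the protease acrosin, was at 348 and 273 FPKM in the wild type and 162 and 108 FPKM in the knockout (limma adjusted p = 0.0602). Zpbp2 was at 620 and 604 FPKM against 765 and 527 FPKM (limma adjusted p = 0.921).

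**Figure D2:**
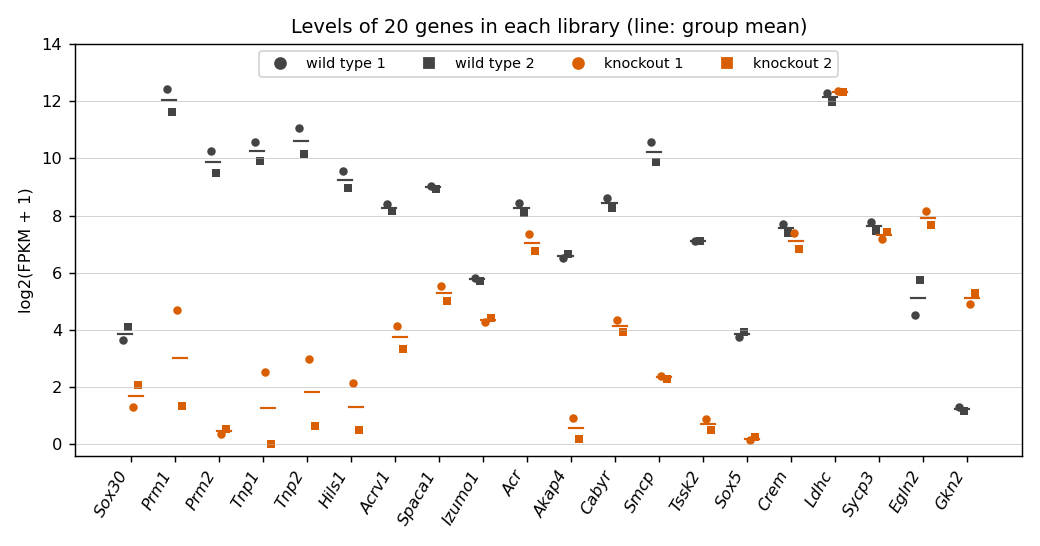
Levels of 20 genes, as log2(FPKM + 1), in each of the 4 libraries (circles for library 1 and squares for library 2 of a genotype; short lines are group means). Transition proteins and protamines, Akap4, Tssk2 and Sox5 drop toward 0 in the knockout, whereas Ldhc has 5003 and 4016 FPKM in the wild type and 5186 and 5056 FPKM in the knockout; several of these genes were picked after their values were seen.

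Some genes of the manchette and head shaping list and some of the spermatid kinase and phosphatase list fell too. In the manchette and head shaping list 14 of 37 tested genes fell, 0 rose and 23 did not pass (15 and 0 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 0.00703; adjusted p = 0.555 with an estimated correlation). Oaz3, the testis antizyme, fell from 941 and 661 FPKM to 2.14 and 0.246 FPKM, and Sun5 from 125 and 106 FPKM to 1.41 and 0.0601 FPKM. Ccdc54 and Spata3 fell as well, with log2 changes of -6.63 and -6.49. Of 27 spermatid kinase and phosphatase genes, 9 fell, 0 rose and 18 did not pass (13 and 0 adjusted over the list alone), with a median of -1.15 (camera adjusted p = 0.00993; adjusted p = 0.555 with an estimated correlation). Tssk1, Tssk2, Tssk6 and Camk4 are counted among the falls of the chromatin condensation list too, and Tsks among those of the manchette list. Tssk2, a testis-specific serine kinase, fell from 137 and 136 FPKM to 0.851 and 0.429 FPKM. Tssk3 stood at 49.3 and 55.7 FPKM in the wild type and at 0 and 0.0696 FPKM in the knockout, and Tssk6 and Dusp21 were listed at 0 in both knockout libraries. The median of the manchette list was -0.50 without wild-type library 2, and that of the kinase list -0.64 without knockout library 2.

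Flagellar genes split. In the flagellum and axoneme list 12 of 87 tested genes fell, 0 rose and 75 did not pass, with the same counts of 12 and 0 adjusted over the list alone, and the list as a whole did not pass (median -0.33, camera adjusted p = 0.376). After quantile normalization it passed (median -0.22, camera adjusted p = 0.0181). The fallen members included Odf3, from 260 and 216 FPKM to 1.90 and 0 FPKM, and Ropn1, from 1072 and 820 FPKM to 10.7 and 5.90 FPKM. Akap4 and Cabyr, of the fibrous sheath around the sperm tail, fell with log2 changes of -6.02 (SE 0.39) and -4.30 (SE 0.31). By contrast Tekt1 and Odf2, picked after their values were seen, were at 621 and 528 against 565 and 365 FPKM and at 434 and 657 against 771 and 498 FPKM (limma adjusted p = 0.517 and 0.718).

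Sperm metabolism and ion channel genes included some of the clearest losses. Of 39 tested genes 10 fell and 0 rose (14 and 1 adjusted over the list alone), with a median of -0.71 (camera adjusted p = 0.0294; adjusted p = 0.555 with an estimated correlation). Smcp, of the mitochondrial capsule, fell from 1533 and 946 FPKM to 4.26 and 3.85 FPKM. Catsper3, a subunit of the sperm calcium channel, fell from 82.1 and 84.9 FPKM to 0.0481 and 0.0512 FPKM, and Catsper4 from 63.2 and 73.6 FPKM to 0 and 0.0431 FPKM. Gapdhs, the sperm form of a glycolytic enzyme, was at 54.9 and 34.7 FPKM in the wild type and listed at 0 in both knockout libraries. The call on this list ended without wild-type library 2 (camera adjusted p = 0.0658) and with no filter on low values (0.0645).

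Of 47 tested regulators of postmeiotic transcription and translation 9 fell and 0 rose, with the same counts adjusted over the list alone. The median was -0.51 (camera adjusted p = 0.0450; adjusted p = 0.659 with an estimated correlation). Sox30, the targeted gene, is among the 9 and entered the list test, which was not run without it. Hmgb4 is counted among the falls of the chromatin condensation list too, and Spz1 among those of the manchette list. Fhl5, an activator of CREM, fell from 212 and 145 FPKM to 0.0598 and 0.0637 FPKM, Spz1 from 175 and 169 FPKM to 5.84 and 4.89 FPKM, and Sox5 from 12.5 and 14.4 FPKM to 0.118 and 0.181 FPKM. Crem itself, a regulator of postmeiotic genes named after its values were seen, was at 209 and 167 FPKM in the wild type and 166 and 114 FPKM in the knockout (limma adjusted p = 0.394). This list call was near the threshold: it ended without wild-type library 2 (camera adjusted p = 0.161), knockout library 1 (0.0735, median -0.89) or knockout library 2 (0.0938, median -0.22), with median-ratio scaling (0.0633) and after the GC correction (0.101).

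Of 27 tested genes in the sex-linked spermatid list 19 fell and 0 rose (21 and 1 adjusted over the list alone), with a median of -2.25 (camera adjusted p = 5.1e-08; adjusted p = 0.555 with an estimated correlation). The median was -3.72 with a mean FPKM of at least 5, -1.32 with no filter on low values, -3.87 with a pseudocount of 0.1 and -1.15 with a pseudocount of 5. Cypt3, of a family of small basic spermatid proteins, fell from 164 and 133 FPKM to 1.75 FPKM and 0. Cypt1 fell with a log2 change of -5.83. Cypt4, which had the largest fall in the list at -7.16, lies on chromosome 9 in the annotation and is not sex-linked. Members of the Cypt family resemble each other in sequence and may share reads, so their separate values are uncertain. Akap4 belongs to this list too, as do Akap14 of the flagellum list and Actrt1 and Cylc1 of the acrosome list.

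The same GC correction moved the median of all genes tested from -0.23 to 0.02. List medians after it were -2.07 for the acrosome, -1.49 for chromatin condensation, -1.45 for the sex-linked list, -0.79 for the kinases, -0.44 for the manchette list, -0.21 for the metabolism and ion channel list, -0.17 for the regulators and -0.08 for the flagellum list. Camera adjusted p after the correction was 6.7e-08 for the sex-linked, 8.0e-04 for the manchette and 0.0287 for the metabolism and ion channel list.

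The counts of fallen list members moved with the libraries used, as did those of all genes. Without wild-type library 1, without knockout library 1 and without knockout library 2, in that order, the fallen genes were 8, 40 and 33 in the acrosome list, 8, 19 and 20 in chromatin condensation, 2, 19 and 16 in the manchette list and 5, 16 and 12 among the kinases. They were 3, 30 and 20 in the flagellum list, 5, 20 and 15 in metabolism and ion channels, 2, 23 and 13 among the regulators and 5, 23 and 20 in the sex-linked list. Rises in these lists numbered 0 in each without wild-type library 1, from 0 to 4 without knockout library 1 and from 1 to 10 without knockout library 2, with the 10 in the flagellum list, whose median ranged from -0.50 without knockout library 1 to -0.19 without knockout library 2.

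**Figure D3:**
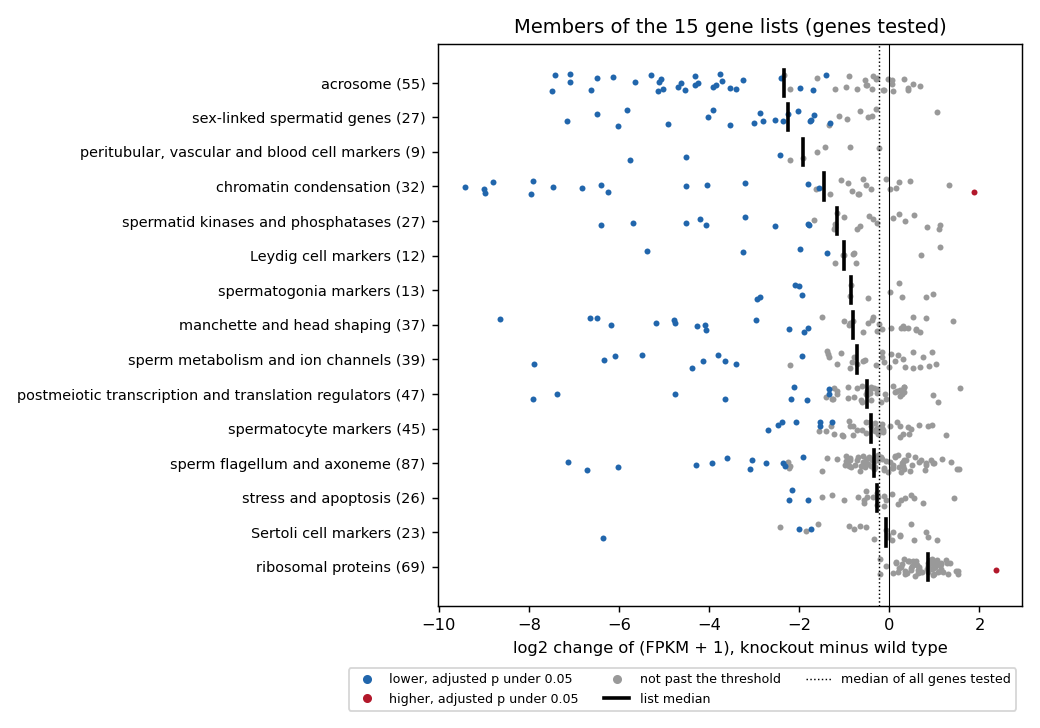
Log2 change of FPKM + 1 (horizontal axis) of each tested member of the 15 gene lists, with blue for genes that fell, red for genes that rose and grey for the others. Black bars are list medians, from -2.34 for the acrosome list to 0.87 for ribosomal proteins, and the dotted line is the median of all genes tested, -0.23.

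Ribosomal protein genes lay above the other genes, with a median of 0.87 over 69 tested members (camera adjusted p = 8.0e-13; adjusted p = 0.555 with an estimated correlation). Only Rpl26 passed by itself, at 46.7 and 41.6 FPKM in the wild type and 141 and 378 FPKM in the knockout, and adjusted over the list alone 0 passed, with 1 passing over all genes tested. Rpl41 was at 2126 and 1516 FPKM against 2984 and 5156 FPKM (limma adjusted p = 0.101). The direction was positive under each scaling, with medians of 0.94 after median-ratio scaling and 1.01 after quantile normalization. Its size depended on knockout library 2, without which the median was 0.47. The number of members that rose varied, with 46 without knockout library 1, 4 without knockout library 2, 0 without either wild-type library and 11 after the GC correction. Rpl26 no longer passed with a pseudocount of 0.1 (limma adjusted p = 0.0520) or with no filter on low values (0.0932). Many processed copies of these genes exist in the genome, so their values may hold reads of such copies.

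Most of the named genes that rose had modest levels. Of all 178 risen genes, 71 had a wild-type mean under 5 FPKM and 18 of 100 FPKM or more. Among the 9124 genes tested these numbered 3394 and 1021, a similar spread. Apoc2, an apolipoprotein, rose from 1.18 and 0.242 FPKM to 22.8 and 36.7 FPKM, an increase of 4.18 on the log2 scale (SE 0.46, limma adjusted p = 0.00258). Gkn2 rose from 1.46 and 1.22 FPKM to 29.2 and 37.9 FPKM and P2rx5, an ATP-gated ion channel, from 0.124 and 0.245 FPKM to 13.3 and 7.34 FPKM. Fhit rose from 0.432 and 0.310 FPKM to 10.6 and 10.7 FPKM. Higher levels were reached by Egln2, a prolyl hydroxylase of the oxygen-sensing pathway, from 21.7 and 52.8 FPKM to 286 and 201 FPKM, and by Amdhd2, from 44.3 and 57.0 FPKM to 327 and 265 FPKM. Ccl27b rose from 20.9 and 17.1 FPKM to 100 and 136 FPKM. Agr3 was listed at 0 in both wild-type libraries and stood at 4.80 and 6.36 FPKM in the knockout, and Vaultrc5 was listed at 0 against 2.20 and 12.2 FPKM. The named genes that rose most also held Cldn5, Rprml and Akr1c19, with log2 changes of 2.72, 2.50 and 2.46. With no filter on low values Egln2, Cldn5, Rprml and Vaultrc5 no longer passed (limma adjusted p = 0.0633, 0.0649, 0.0599 and 0.145). Vaultrc5, at limma adjusted p = 0.0497, also missed the threshold with a pseudocount of 5 (0.0900), robust empirical Bayes (0.0513) and no mean-variance trend (0.0515).

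Outside these lists, the largest falls included Tmsb15a and Dnajc5b, at 395 and 245 FPKM and at 352 and 256 FPKM in the wild type and listed at 0 in both knockout libraries. Aif1 fell from 351 and 290 FPKM to 1.23 FPKM and 0, and Rnf151, a ring finger protein gene, from 571 and 422 FPKM to 1.53 and 1.22 FPKM.

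Neither list of markers of earlier germ cells passed with camera. Of 45 spermatocyte markers tested 7 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.281). That median ranged from -0.74 without knockout library 1 to -0.15 without knockout library 2. The fallen members included Rec8, Syce2, Tex11 and Tex15. Sycp3, a protein of the synaptonemal complex named after its values were seen, was at 217 and 177 FPKM in the wild type and 143 and 172 FPKM in the knockout (limma adjusted p = 0.482). Of 13 spermatogonia markers 5 fell and 0 rose (5 and 1 adjusted over the list alone), with a median of -0.85 (camera adjusted p = 0.290), while fry, which does not compare the list with other genes, gave adjusted p = 0.0388. Stra8, Sohlh1 and Dmrt1, at 7.20 and 5.48, 2.94 and 3.60, and 2.62 and 3.48 FPKM in the wild type, were listed at 0 in both knockout libraries, and Crabp1 fell from 17.4 and 11.6 FPKM to 2.95 FPKM and 0.

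Some genes of the somatic and blood cell marker lists were lower in the knockout, while others were not. The values do not show which cells these transcripts came from, so a fall need not be a loss of somatic cells. Hba-a1, a hemoglobin gene, was at 220 and 109 FPKM in the wild type and at 7.45 FPKM in knockout library 1, with a value next to 0 in knockout library 2. Insl3, a Leydig cell hormone, was at 54.8 and 30.3 FPKM in the wild type and next to 0 in both knockout libraries. Such values next to 0, as for Cypt1 and Cypt4, differ from listed zeros and may come from reads shared between similar sequences. Hba-a2, a near-identical copy of Hba-a1, was next to 0 in wild-type library 1 but not in wild-type library 2, so the separate values of these genes are uncertain. Of 9 peritubular, vascular and blood cell markers 3 fell and 0 rose, with the same counts adjusted over the list alone (median -1.93, camera adjusted p = 0.0294; adjusted p = 0.555 with an estimated correlation), namely Hba-a1, Hbb-b1 and Acta2. Among 12 Leydig cell markers 4 fell and 0 rose, again with the same counts adjusted over the list alone (median -1.01, camera adjusted p = 0.0589): Insl3, Cyp51, Cyp17a1 and Idi1. The fall of Idi1, -1.37 on the log2 scale, was -0.62 after the GC correction (limma adjusted p = 0.303), and it did not pass with quantile normalization (0.112), a pseudocount of 0.1 (0.0550) or no filter on low values (0.0561). The Leydig cell list passed with no filter on low values (camera adjusted p = 0.00901), a mean FPKM of at least 5 (0.0350), median-ratio scaling (0.0474), quantile normalization (0.0371) and without wild-type library 1 (0.0414), with adjusted p = 0.555 for an estimated correlation. It did not pass without wild-type library 2 (0.0642), knockout library 1 (0.0972) or knockout library 2 (0.208). Its median ranged from -1.56 without knockout library 1, with 9 fallen and 1 risen, to -0.63 without knockout library 2, with 4 fallen and 1 risen, and 2 fell without wild-type library 1. Of 23 Sertoli cell markers 3 fell and 0 rose by both adjustments: Cst8, Tsx and Dmrt1, which is in the spermatogonia list too. The list did not pass (camera adjusted p = 0.862), with a median of -0.08 that had no stable direction. It was 0.02 after median-ratio scaling, -0.71 without wild-type library 1, 0.23 without wild-type library 2 and -0.35 without knockout library 1, where 10 fell and 1 rose. Tsx no longer passed after the GC correction (limma adjusted p = 0.0544), with quantile normalization (0.0503), a pseudocount of 0.1 (0.0541) or no filter on low values (0.0767). Defb19, a Sertoli cell marker picked after its values were seen, was at 621 and 764 FPKM against 711 and 935 FPKM and did not pass. The stress and apoptosis list did not pass either (median -0.27, camera adjusted p = 0.862). Its median was 0.27 after quantile normalization, -0.52 without wild-type library 1 and -0.07 without wild-type library 2. Of its 26 tested genes 3 fell, Xbp1, Srxn1 and Mdm2, and 0 rose by both adjustments. The call on the peritubular, vascular and blood cell list ended with no filter on low values (median -0.19, camera adjusted p = 0.338) and when only symbols listed once were used (0.0576). The median of that list ranged from -2.63 without knockout library 1 to -1.35 without wild-type library 2. Other named genes lost the call both with a pseudocount of 0.1 and with no filter on low values: Hba-a1 (limma adjusted p = 0.0932 and 0.0763), Acta2 (0.114 and 0.0880), Srxn1 (0.107 and 0.0885), Rec8 (0.0592 and 0.0605), Syce2 (0.0593 and 0.0982) and Crabp1 (0.153 and 0.122).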

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

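The correction for GC content and the crossed pairing were tests chosen only after the data were seen. The count of fallen genes was 1221 and moved beyond 1.5 times only with a mean FPKM of at least 5, which tests fewer genes (787), and without 1 library, where it ranged from 0 to 3071 and the total from 0 to 4055. The count of risen genes, 178, was less stable: 113 with a pseudocount of 0.1, 62 with no filter on low values, 608 after quantile normalization, 319 after the GC correction, and from 0 to 984 without 1 library. Leaving out a knockout library leaves the smaller spread of the wild-type pair to set the error. Leaving out wild-type library 2 ended all calls, and the cause was not tested. At an adjusted p under 0.1 the total was 2058, with 1644 fallen and 414 risen. The labels do not say what a shared library number marks. Deviations of same-numbered libraries correlated at r = -0.20 across genes, which cannot decide whether such libraries shared a batch. With the replicate block 1056 genes fell and 82 rose, of which 1030 and 78 were shared with the unblocked fit, and the regulator list had adjusted p = 0.0683. A crossed pairing gave 1416 and 390.

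Sox30 had the same change with no filter on low values, -2.19, but limma adjusted p = 0.0660, as more genes were tested. Without 1 library it ranged from -2.57 to -1.81. With an estimated correlation no list passed: the adjusted p was 0.659 for the regulators and 0.555 for the acrosome, chromatin condensation, metabolism and ion channel, manchette, kinase, peritubular and blood, ribosomal and sex-linked lists. That test had little power on 2 residual degrees of freedom. It cannot decide whether correlation between members accounts for the calls. With fry, ribosomal proteins (0.184), regulators (0.0513) and peritubular and blood markers (0.0591) did not pass, while the spermatogonia markers did (0.0388). The Leydig cell list, at 0.0589, passed in 5 of the other settings (0.00901 with no filter on low values, 0.0350 with a mean FPKM of at least 5, 0.0474 with median-ratio scaling, 0.0371 with quantile normalization and 0.0414 without wild-type library 1), and the flagellum list with quantile normalization (0.0181). With no filter on low values the metabolism list had 0.0645, the regulators 0.0649 and the peritubular and blood markers 0.338. The peritubular and blood markers had 0.0576 over symbols listed once. The regulators also missed the threshold with median-ratio scaling (0.0633), without the trend (0.0509) and after the GC correction (0.101). The cause was not tested. Without 1 library the adjusted p ranged from 9.5e-04 to 0.0658 for the metabolism list and from 0.0414 to 0.161 for the regulators.

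Directions of lists are those given by camera, relative to the other genes, and need not match the sign of the list median. Among lists that had not passed they turned for the spermatogonia markers with a mean FPKM of at least 5 (camera adjusted p = 0.932). They also turned for the stress list after quantile normalization (0.852). The medians of the spermatocyte and stress lists stayed negative in every fit without 1 library. Without 1 library the adjusted p ranged from 0.267 to 0.968 for the spermatocyte markers, from 0.194 to 0.705 for the Sertoli cell markers and from 0.472 to 0.968 for the stress list, each with a turn of direction in at least 1 of the 4 fits. The cause was not tested. No named gene turned direction under any alternative. Their selection made this nearly certain: all but Rpl41 had passed the threshold, and every gene past it had both knockout values on the same side of both wild-type values. It is therefore no sign of stability. Of the 70 named genes besides Sox30, 46 lost the call without wild-type library 1 and 69 without wild-type library 2, 13 with no filter on low values and 9 with a pseudocount of 0.1. With the replicate block Idi1 (0.116) and Tsx (0.0625) lost it. Depth limits the low genes most, since values next to 0 rest on few or no fragments, and only relative depth is known.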

Other observations

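The tests of GC content, of X-linked genes and of genes at 0 described here were chosen only after related values had been seen. The genes most abundant in wild-type spermatids largely kept high levels in the knockout. Of the 20 genes with the highest wild-type mean, a set picked after the values were seen, Prm1 fell and 0 rose. Fabp9, a fatty acid binding protein gene of the testis, was at 7093 and 5446 FPKM in the wild type and 8688 and 13636 FPKM in the knockout (limma adjusted p = 0.165). Ldhc, the testis lactate dehydrogenase, was at 5003 and 4016 FPKM against 5186 and 5056 FPKM (limma adjusted p = 0.659), and Tcte3 at 4397 and 3319 FPKM against 7470 and 9681 FPKM (limma adjusted p = 0.0539). Actb, the gene of a cytoskeletal actin, outside that set and also picked after its values were seen, fell from 107 and 70.1 FPKM to 25.7 and 17.2 FPKM (limma adjusted p = 0.0180).

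X-linked genes beyond the fixed list of sex-linked spermatid genes were often lower in the knockout. Of 306 X-linked genes tested 125 fell, 40.8%, and 0 rose, against 1071 fallen and 175 risen among 8683 autosomal genes (Fisher's exact test for the fallen, adjusted p = 1.3e-32, over 42 tests). The median log2 change was -1.23 on the X and -0.20 on the autosomes, and -1.15 over the 273 X-linked genes outside the fixed lists, of which 105 fell. Of examples picked after their values were seen, Prdx4, a peroxiredoxin gene, fell from 158 and 124 FPKM to 10.3 and 5.12 FPKM, Pdk3 from 43.7 and 43.5 FPKM to 4.65 and 2.66 FPKM, and Acot9, at 45.6 and 39.3 FPKM in the wild type, was listed at 0 in both knockout libraries. Of 5 Y-linked genes 4 fell (Fisher's exact test, adjusted p = 0.0197), Eif2s3y, Ube1y1, Zfy2 and the pseudogene Tspy-ps, of which only Tspy-ps lies outside the fixed list. Genes treated one by one are not independent replicates, so these p-values describe these libraries. The number of fallen X-linked genes was 64 without wild-type library 1, 0 without wild-type library 2, 197 without knockout library 1 and 171 without knockout library 2, while the X median stayed between -1.62 and -1.17. Rises on the X numbered 0 in these fits without a wild-type library, 11 without either knockout library and 9 after the GC correction. After that correction the fallen X-linked genes still passed the exact test (106 of 306, adjusted p = 8.7e-22), and the Y-linked genes, 3 of 5, did not (adjusted p = 0.368). Among autosomes, fallen genes were fewer than elsewhere on chromosomes 17 and 11 (adjusted p = 0.0208 and 0.0285) and risen genes more frequent on chromosomes 17 and 7 (adjusted p = 0.0285 and 0.0171). No autosome passed after the GC correction, with 44 of 442 and 81 of 731 fallen on chromosomes 17 and 11 (adjusted p = 0.614 and 0.673) and 19 of 442 and 24 of 684 risen on chromosomes 17 and 7 (adjusted p = 0.807 and 1).

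GC content and level were weighed as an explanation of the X-linked pattern, since X-linked transcripts had a median GC content of 45.2%. Among 10000 autosomal lists of 306 genes matched on GC content, in 5 classes, and on wild-type level, 0% had a median as low as -1.23, and the lowest reached -0.75, which argues against both as the whole cause. A larger share of spermatocytes, in which the sex chromosomes are silenced, stays open. The spermatocyte markers had a median of -0.40 with 7 fallen and 0 risen, but the 95% bootstrap interval over genes, -0.80 to -0.22, holds the median of all genes, -0.23. The marker median was -0.56 without wild-type library 1, -0.31 without wild-type library 2, -0.74 without knockout library 1 and -0.15 without knockout library 2. The medians of all genes in these fits were -0.36, -0.13, -0.40 and -0.06, each above that of the markers. After the GC correction the X median was -0.65, against 0.04 on the autosomes and -0.07 for the spermatocyte markers. A dependence of postmeiotic sex-linked transcription on Sox30, direct or through a halt in development, and reads shared between copies of X-linked gene families were not tested and stay open.

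Changes between genotypes also followed the GC content of the transcripts. The median log2 change was -0.70 in the lowest of 5 equal classes of GC content and 0.36 in the highest. Drift from library to library is argued against, because the span over these classes was at least 0.784 in the pairs of different genotype and 0.224 and 0.323 within the genotypes. The trend as the whole cause of the falls is argued against too, since 83.2% of them, 998 of 1200, passed again after the correction, as did 128 of 175 rises. The trend had a span of 0.885 in genes past no threshold, so a bias tied to how the knockout libraries were made may be present and cannot be told apart from genotype, because no label separates preparation from genotype.

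More genes were listed at 0 in the knockout libraries, 394 and 771 of the genes tested against 13 and 15 in the wild type. Shallower sequencing is argued against, since the lower of the knockout libraries' relative depths was 1.16 against 1 for wild-type library 1. Among genes with a mean of 1 to 5 FPKM in the other genotype, 212 of 3651 (5.81%) were at 0 in 1 knockout library and at 1 FPKM or more in the other, against 0 of 3205 in the wild-type pair. Each set was picked on its level in the other genotype, and falls outnumbered rises. The sets are thus unlike, and part of the contrast may come from that choice. Whether random loss of transcripts or real differences between the knockout libraries account for the 212 genes stays open. Of 2961 genes with a wild-type mean of at least 20 FPKM, 54 were at 0 in both knockout libraries where independent loss with 1 chance for all genes would give 3.34, a ratio of 16.2 (8.88 within classes of GC content, length and level), which leaves random loss open, since a chance that differs by gene would also give shared zeros. For the 96 such genes at 0 in only 1 knockout library, chance loss of transcripts present at the wild-type level is argued against, as the other knockout library had a median of 0.791% of the wild-type mean (quartiles 0.203% and 1.88%), with 95 of 96 below it, and a loss tied to genotype or to how the knockout libraries were made stays open.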
